A study of Homo sapiens with 24 samples.

How the data were processed

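Total RNA from MCF7 and MDA-MB-231 cells stably expressing GFP, GFP-Numb4, GFP-Numb5 or GFP-Numb6 was hybridised to Affymetrix 3′ expression arrays, with 3 arrays in each of 8 groups. Per the labels, the lines were grown under selection in different media, and the biotin-labelled target was made with a random-primed labelling kit meant for whole-transcript arrays, which does not match a 3′ array. The deposited values are linear signal intensity for 54675 probe sets, 62 of them controls, and the authors had scaled every array to the same mean after trimming 2% of probe sets at each end: the trimmed mean is 150 on all 24 arrays. The software and the background step are not given in the sources used here, and no detection calls were used. No column was left unused. Array signals have no counting depth. The number of arrays limits the precision. The labels call the 3 replicates of a group biological but do not say whether transfections were independent.

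The log2 of the signal was analysed with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for tables and Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3 for the figures. Probe sets were annotated from a probe annotation listing of 42898 of them, 41097 with a single symbol and 1801 with several, while 11777 were not listed. Only probe sets with a single symbol were used, and for each gene the probe set with the highest mean over the 24 arrays, which left 19775 genes. No filter on dim signal was applied. Chromosome positions were not used. Folds were computed with signals under 16 raised to 16 and are given as "at least" where this applied.

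Within each line, a model with 1 mean per group was fitted to the 12 arrays with lmFit and eBayes, and each form was compared with GFP and with the other forms. Tests were two-sided with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. A moderated F-test covered the 4 transfections of a line. A fit to all 24 arrays gave the difference of each form's effect between the lines and the comparison of the GFP cells. The 27 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 27 lists of a comparison. Counts of list members are given over all genes and, where stated, adjusted over the list alone. Overlaps between comparisons were set beside the product of their counts divided by the number of genes, by direction, and beside 50 simulations of 4 groups without any change, GFP included, with the spread of each gene. Each form was also compared with a different GFP array in all 6 assignments, with the spread from the form arrays, which assumes that a lone GFP array varies like them. To test the difference between lines, arrays were exchanged between them within a transfection, each line centred on its mean. In simulated data, 200 of 19775 genes were changed in the real groups' spread, with 4 to 12 false calls. The test recovered 55.2% to 70.1% of log2 changes of 1 in MCF7 and 82.1% to 89.6% in MDA-MB-231. For changes of 0.5 recovery was 10.4% to 16.4% and 29.9% to 49.3%. It was not split by signal.

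Genes were named by a rule fixed before the data were examined. For each form against GFP it took NUMB, the 10 largest rises and 10 largest falls among called genes whose 3 arrays of each group did not overlap, the 4 members with the smallest p of each list that passed, and NOTCH1, HES1, HEY1, TP53, MDM2, CDKN1A and NUMBL. Between forms and for differences between lines it took the 5 largest rises and falls (without the condition on separate arrays for the lines), and for the GFP cells the 5 luminal and 5 basal markers with the largest difference. The alternatives were quantile normalization, leaving out the dimmest genes, testing every probe set, a variance trend, replicate number as a block, the spread from all 24 arrays, only the arrays compared, leaving out 1 array at a time, an estimated correlation for the lists and an absolute log2 change of at least 0.58 for overlaps. After seeing the data, signals under 16 set to 16 and leaving out the 3 MCF7 arrays with a beta-actin ratio over 2.2 were added. XIST and Y-linked genes were left out.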

Results

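Gene expression was measured in 2 human breast cancer cell lines, MCF7 (estrogen receptor positive, luminal) and MDA-MB-231 (estrogen receptor negative, basal and mesenchymal), each stably transfected with green fluorescent protein (GFP) alone or with GFP fused to the Numb4, Numb5 or Numb6 form of NUMB, an endocytic adaptor known as an inhibitor of Notch signalling. Each of the 8 groups held 3 arrays, 24 in all, with 1 signal per probe set and array. The median signal per array was 22.6 to 29.5 in MCF7 and 19.0 to 22.3 in MDA-MB-231. Arrays of the same group correlated at r = 0.979 to 0.987 in MCF7 and 0.984 to 0.993 in MDA-MB-231 across bright probe sets, and arrays of different groups of a line at 0.920 to 0.965 and 0.870 to 0.963; probe sets are not independent replicates. The 3′ to 5′ signal ratio of beta-actin, a sign of RNA integrity, averaged 1.94 ± 0.366 (SD, n = 3) in MCF7 GFP, 1.56 ± 0.265 in Numb4, 1.87 ± 0.473 in Numb5 and 1.98 ± 0.373 in Numb6, and it was 2.36, 2.41 and 2.40 on MCF7 GFP array 1, Numb5 array 3 and Numb6 array 2. In MDA-MB-231 it averaged 1.41 ± 0.0864, 1.66 ± 0.0896, 1.61 ± 0.199 and 1.5 ± 0.128 in the same order of groups. The p-values below measure the spread between biological replicates, perhaps of 1 transfection. The 2 lines differed in growth medium and array run, so line, medium and run cannot be told apart.

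The GFP cells of the 2 lines were compared first, as a check of the labels through known markers. MCF7 GFP cells carried the luminal markers and MDA-MB-231 GFP cells the basal ones. ESR1, the estrogen receptor, had a signal of 1298 ± 82.7 in MCF7 and 5.42 ± 2.91 in MDA-MB-231, at least 81.0-fold apart. GATA3, a luminal transcription factor, was 50.3-fold higher in MCF7 (16852 ± 1160 against 334.8 ± 12.4), AGR2 was 120.5-fold higher, and the luminal genes ERBB3 and FOXA1 were at least 83.1-fold and 35.6-fold higher. In MDA-MB-231, the calcium-binding protein gene S100A4 was 126.6-fold higher (4368 ± 180.4 against 34.5 ± 2.15), ANXA1 102.8-fold higher, and MSN, LOX and CD74 at least 228.6-fold, 65.4-fold and 18.8-fold higher. Where any array of a compared group lay under a signal of 16, it was raised to 16, and the fold is then given as "at least", the lower of the ratios of geometric and arithmetic means. Other folds are ratios of geometric means. Of 14 luminal markers, 14 were lower in MDA-MB-231 (median log2 difference −4.48, adjusted p = 4.98e-11), and of 17 basal and mesenchymal markers, 17 were higher (median 4.90, adjusted p = 2.25e-17). Adjusted over the list alone, the counts were the same 14 and 17. With signals under 16 set to 16 these medians were −4.22 and 4.23. Between the 2 lines, 9939 of 19775 genes differed at an adjusted p under 0.05, 4025 higher and 5914 lower in MDA-MB-231, with a median log2 difference over all genes of −0.32, and of −0.12 after quantile normalization.

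The level of NUMB was examined in every group as a check of the transfections. Of 3 probe sets annotated to NUMB and to the uncharacterised locus LOC101928143, 2 were brighter. In MDA-MB-231, the brightest read 442.5 ± 38.9 in Numb4 cells, 316.5 ± 33.1 in Numb6 cells and 229.9 ± 10.8 in Numb5 cells, against 203.9 ± 15.6 in GFP cells. The log2 change was 1.12 in Numb4 (adjusted p = 0.000335), 0.63 in Numb6 (adjusted p = 0.00699) and 0.17 in Numb5 (adjusted p = 0.435, not passed). The second probe set with this annotation changed by 1.38 in Numb4 (adjusted p = 0.00156) and 1.08 in Numb6 (adjusted p = 0.00564) and did not pass in Numb5 (0.49, adjusted p = 0.153). In MCF7 none of the 3 forms passed for either probe set: for the brighter the log2 changes were 0.40, 0.35 and 0.30 in Numb4, Numb5 and Numb6 (adjusted p = 0.228, 0.307 and 0.412), and for the other 0.41, 0.05 and −0.23 (adjusted p = 0.475, 0.957 and 0.734). The single probe set that stood for NUMB in the gene-level test was dim, with group means from 17.2 to 35.7, and did not pass in any of the 6 comparisons with GFP. Its log2 changes in Numb4, Numb5 and Numb6 cells were −0.51, −1.02 and −0.25 in MCF7 (adjusted p = 0.629, 0.276 and 0.830) and 0.39, −0.44 and −0.22 in MDA-MB-231 (adjusted p = 0.581, 0.537 and 0.776). Whether these probe sets lie in the part of NUMB carried by the transgenes is not known from the sources used here, so the values are a limited check.

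**Figure D1:**
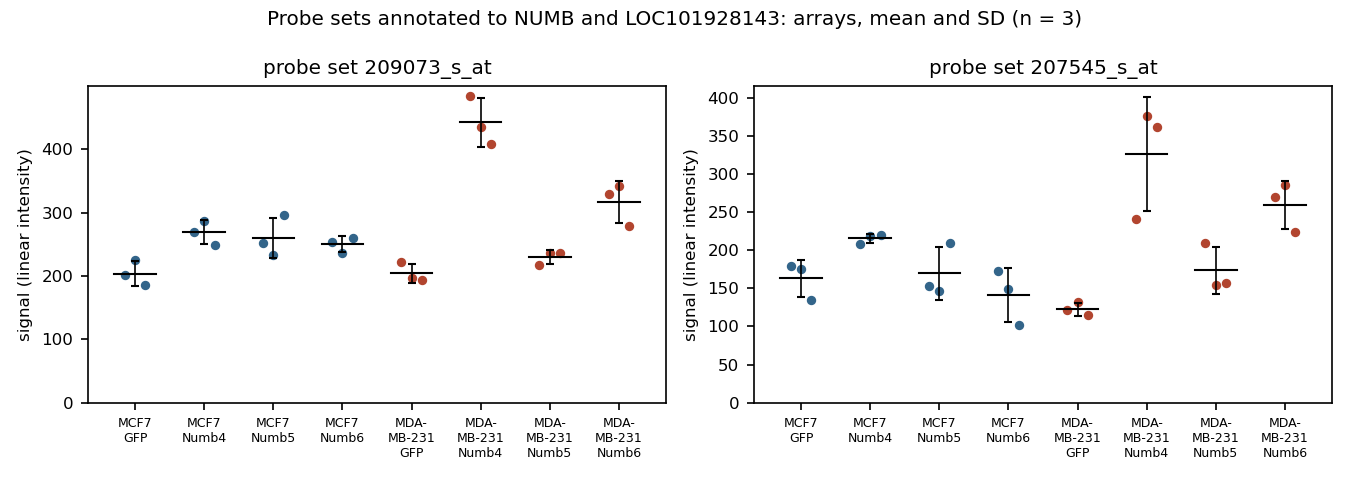
Signal (linear, arbitrary units) of the 2 probe sets annotated to NUMB and LOC101928143 on each array by group, with the mean and SD of 3 arrays. In MDA-MB-231 the Numb4 arrays average 442.5 and 326.1 on the 2 probe sets, against 203.9 and 122.8 on the GFP arrays.

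In MCF7 cells, Numb4 was set against GFP to find the genes that differed between these cells. The replicates of a group may not be independent transfections. An effect of a form and a difference of its transfected line therefore cannot be told apart here or in the comparisons below. GJA1, the gap junction protein connexin 43, read 1392 ± 121.5 in Numb4 cells and 6.88 ± 6.11 in GFP cells, at least 86.8-fold higher (adjusted p = 0.00130). CEACAM5, the carcinoembryonic antigen, rose 45.2-fold to 4604 ± 272.9 (adjusted p = 1.73e-08), S100P, a calcium-binding protein, rose 37.4-fold to 5843 ± 174 (adjusted p = 2.78e-07), CP, ceruloplasmin, rose 43.6-fold to 819.8 ± 48.4, and MARCKS, a substrate of protein kinase C, rose 40.1-fold to 1170 ± 17.6. RAI14, UPK3A, BPIFB1, KRT4 and RNF128 rose at least 18.7-, 16.2-, 10.5-, 7.71- and 7.61-fold. MAOB, a monoamine oxidase, fell from 727.5 ± 14.3 to 11.1 ± 5.69 (at least 45.5-fold, adjusted p = 2.97e-05), and the cadherin family genes PCDH10 and PCDH7 fell at least 27.3- and 21.04-fold. The interferon-stimulated gene IFI27 fell from 268.3 ± 60.5 to 8.30 ± 5.35 (at least 16.5-fold) and BCL2, which blocks apoptosis, from 226.7 ± 14.7 to 7.68 ± 8.72 (at least 13.7-fold). MMP16, ANKS1B, COL4A6, CDKN2B and MALRD1 also fell, by at least 20.8-, 10.5-, 6.95-, 6.62- and 5.28-fold. The ANKS1B call (adjusted p = 0.0164) depended on single arrays, with adjusted p between 0.00641 and 0.0614 without 1 array at a time and no call without GFP array 2 or 3 or Numb4 array 1 or 3.

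Of the 27 gene lists fixed before the data were examined, 7 passed in this comparison, and 2 of them also with an estimated correlation. Of 17 basal and mesenchymal markers, 9 rose, 1 fell and 7 did not pass (10 up and 1 down adjusted over the list alone; median log2 change 0.78, adjusted p = 2.87e-07; adjusted p = 0.00664 with an estimated correlation). Among them IGFBP3, which binds insulin-like growth factors, rose 9.11-fold, the matrix protein gene TGFBI 4.70-fold, the kinase gene LYN 4.02-fold and S100A4 3.77-fold. Of 9 replication-dependent histone genes, 7 fell and 2 did not pass (0 up and 7 down adjusted over the list alone; median −1.51, adjusted p = 5.40e-09; adjusted p = 0.00664 with an estimated correlation). H2BC12 fell from 3883 ± 143.6 to 1256 ± 75.6 and H2AC6, H2BC21 and H2BC5 fell 3.65-, 3.38- and 2.86-fold. Such messages as a class mostly lack poly(A) tails, and the list was fixed as a sign of RNA quality. Whether the named genes lack tails was not tested. The beta-actin ratio was not higher in Numb4 (1.56 ± 0.265) than in GFP (1.94 ± 0.366). Of 18 epithelial markers, 5 rose and 13 did not pass (6 up and 0 down adjusted over the list alone; adjusted p = 0.00803, and adjusted p = 0.0720 with an estimated correlation): KRT7 rose 8.86-fold, CLDN4 2.43-fold, OCLN 1.62-fold and RAB25 1.39-fold. The RAB25 call was lost with the spread taken from all 24 arrays (adjusted p = 0.746), from the 6 arrays alone (0.0761) and without the arrays of high beta-actin ratio (0.0876). Of 19 NF-κB targets, 5 rose, 1 fell and 13 did not pass (7 up and 1 down adjusted over the list alone; adjusted p = 0.00481, and adjusted p = 0.105 with an estimated correlation). TNFAIP2 rose 2.65-fold, TNFAIP3 2.46-fold and RELB at least 3.71-fold, and the stress-response gene IER3 fell 1.82-fold.

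Of 21 hypoxia response genes, 5 rose, 1 fell and 15 did not pass (6 up and 2 down adjusted over the list alone; adjusted p = 0.0314, and adjusted p = 0.322 with an estimated correlation). ADM rose 6.48-fold, NDRG1 3.98-fold and HK2 1.91-fold, and BNIP3 fell 2.31-fold. Of 27 Notch receptors, ligands and processing genes, 5 rose and 22 did not pass (5 up and 0 down adjusted over the list alone; adjusted p = 0.0314, and adjusted p = 0.147 with an estimated correlation). DTX4, a Notch-regulating ubiquitin ligase, rose 4.52-fold, the ligand gene DLL1 2.49-fold (adjusted p = 0.215 with the spread taken from all 24 arrays and 0.0614 from the 6 arrays alone), and the protease genes ADAM17 and APH1B 1.46- and 1.53-fold. The call for APH1B was lost without GFP array 1 or 3 or Numb4 array 1 (highest adjusted p 0.0597). RPS19 alone among 20 ribosomal protein genes rose, 1.37-fold (1 up and 0 down adjusted over the list alone), and its call was lost without each of the 6 arrays in turn (adjusted p 0.0563 to 0.111). The ribosomal list passed at an adjusted p of 0.0222, which was 0.104 after quantile normalization, and adjusted p = 0.533 with an estimated correlation. The hypoxia list was not called without GFP array 2 (0.0513) or 3 (0.114) or Numb4 array 1 (0.0569) or 3 (0.0642), the Notch list without GFP array 2 (0.0513) or 3 (0.0568) or Numb4 array 2 (0.106), and the ribosomal list without GFP array 2 (0.104) or Numb4 array 1 (0.0642). In all, 1583 genes changed, 788 up and 795 down, and 724 changed by at least 2-fold. The arrays of the 2 groups did not overlap for 28.3% of all genes, where chance gives 10%. From the 6 arrays alone, ANKS1B, ADAM17, APH1B, OCLN, TNFAIP2, RELB, TNFAIP3, BNIP3 and RPS19 were also not called (adjusted p 0.0551 to 0.104). Without the arrays of high beta-actin ratio ANKS1B, APH1B, TNFAIP2, TNFAIP3 and RPS19 were not called (0.0521 to 0.189). The count was 705 from the 6 arrays alone, 2456 with a variance trend and 2477 with the spread taken from all 24 arrays.

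In MCF7 cells with Numb5, most of the listed genes induced by interferon rose. IFIT1, an antiviral RNA-binding protein, read 4704 ± 136.6 against 31.0 ± 12.6 in GFP cells (162-fold, adjusted p = 0.000112), and IFIT3 1405 ± 153.8 against 22.5 ± 1.31 (62.2-fold, adjusted p = 2.21e-06). OASL and IFI6 rose 11.4-fold to 697.8 ± 66.4 and 9.89-fold to 2163 ± 150, HERC6 rose 10.6-fold, and CMPK2 rose 49.2-fold to 950.3 ± 95.2. SAMD9, XAF1, IFI44L and IFI44 rose at least 47.5-, 45.7-, 20.9- and 17.8-fold. PSMB8 and PSMB9, subunits of the immunoproteasome, and LAMP3, a lysosomal membrane protein, rose at least 10.8-, 11.3- and 11.4-fold. Of 29 interferon-stimulated genes tested, 27 rose, 0 fell and 2 did not pass (28 up and 0 down adjusted over the list alone; median log2 change 3.51, adjusted p = 1.96e-46; adjusted p = 7.89e-06 with an estimated correlation).

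Genes that fell in Numb5 cells included AMIGO2, an adhesion protein, from 2146 ± 141.1 to 145.4 ± 22.3 (14.9-fold, adjusted p = 2.21e-06), the protease gene KLK11 from 993.0 ± 78.0 to 68.3 ± 17.3 (14.9-fold) and RPRM from 326.4 ± 26.0 to 17.3 ± 16.2 (at least 14.4-fold). The chemokine gene CXCL14 fell at least 12.1-fold, ANKS1B at least 10.0-fold, EPHA6, CDH12 and KCNK2 at least 4.11-, 4.03- and 3.66-fold, and DOCK10 and LINC00504 at least 2.50- and 2.43-fold. DOCK10 was not called with signals under 16 set to 16 (adjusted p = 0.0559), nor ANKS1B after quantile normalization (0.0583). CXCL14 and ANKS1B did not pass without each of the 6 arrays in turn (adjusted p 0.0585 to 0.0888 and 0.0580 to 0.148). KCNK2 did not pass without any array but Numb5 array 1 (highest 0.0937), CDH12 without each GFP array or Numb5 array 3 (highest 0.0900), EPHA6 without Numb5 array 1 (0.0549) and LINC00504 without Numb5 array 3 (0.0508). Of 9 replication-dependent histone genes, 5 fell and 4 did not pass (0 up and 5 down adjusted over the list alone; median −0.63, adjusted p = 1.88e-05; adjusted p = 0.0367 with an estimated correlation). H1-2, H2BC21, H2BC12 and H2BC5 fell 2.49-, 2.06-, 1.85- and 1.53-fold. The other 25 of the 27 lists did not pass. In all, 1359 genes changed, 585 up and 774 down, 564 by at least 2-fold, and the groups did not overlap for 27.2% of genes, where chance gives 10%. The count was 818 without GFP array 2, 816 without Numb5 array 1 and 867 without Numb5 array 3, and 507 from the 6 arrays alone. From these, LAMP3, PSMB9, KCNK2, CDH12, ANKS1B, EPHA6, LINC00504, H2BC5 and CDKN1A were not called (adjusted p 0.0595 to 0.156). Without the arrays of high beta-actin ratio the same genes, CXCL14 and HEY1 were not called (0.0535 to 0.231).

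In MCF7 cells, Numb6 was set against GFP in the same way. LCN2, the iron-binding protein lipocalin 2, read 3057 ± 368.9 against 30.2 ± 14.7 (at least 98.4-fold, adjusted p = 4.48e-05), and CEACAM5 rose 30.1-fold to 3072 ± 293 (adjusted p = 6.02e-08). DIO2, a deiodinase that activates thyroid hormone, rose at least 81.1-fold to 1320 ± 78.3, and GJA1 at least 31.0-fold to 499.2 ± 63.4. CFB, a complement factor, rose at least 16.9-fold, WFDC21P 6.73-fold, TCIM 3.90-fold, INHBA 3.198-fold, FGD5 2.23-fold and RNF128 1.32-fold, each as a lower bound. With signals under 16 set to 16, the basis of these folds, the calls for FGD5 and RNF128 were lost (adjusted p = 0.0707 and 0.291). The TCIM call was lost without the arrays of high beta-actin ratio (0.154). INHA, the inhibin alpha subunit, fell 8.32-fold to 102.9 ± 21.4 (adjusted p = 0.000123), PLCXD3 fell 7.99-fold to 41.8 ± 11.7, CXCL14 at least 10.2-fold and LINC00504 at least 2.43-fold. The other 6 of the 10 largest falls were in dim genes: GNB4 and SPINK6 fell at least 1.79- and 1.43-fold. TRIM63 and DIRC1 were not called with signals under 16 set to 16 (log2 −0.145 and −0.0418, adjusted p = 0.702 and 0.701), and BPESC1 and RPH3AL-AS1 lay under 16 in both groups.

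Of the 27 lists, 13 passed in Numb6 cells, 10 of them also with an estimated correlation. Of 17 basal and mesenchymal markers, 9 rose and 8 did not pass (9 up and 0 down adjusted over the list alone; median 1.38, or 1.18 with signals under 16 set to 16; adjusted p = 2.61e-12; adjusted p = 0.000631 with an estimated correlation). IGFBP3 rose 14.0-fold, the caveolin gene CAV1 6.62-fold, S100A4 6.03-fold and TGFBI 2.47-fold. Of 29 interferon-stimulated genes, 12 rose and 17 did not pass (19 up and 0 down adjusted over the list alone; median 1.37, or 0.98 with signals under 16 set to 16; adjusted p = 2.46e-12; adjusted p = 0.000631 with an estimated correlation). SAMD9 rose at least 21.9-fold, OASL 3.52-fold, the transcription factor gene IRF9 3.36-fold and HERC6 2.79-fold. Of 19 NF-κB targets, 6 rose and 13 did not pass (7 up and 1 down adjusted over the list alone; median 0.58, or 0.36 with signals under 16 set to 16; adjusted p = 6.81e-06; adjusted p = 0.0145 with an estimated correlation), among them the feedback inhibitor genes TNFAIP3, up 6.93-fold, and NFKBIA, up 2.52-fold to 4912 ± 584.5, with TNFAIP2 up 6.35-fold and RELB at least 6.60-fold. Of 21 mesenchymal markers, 4 rose and 17 did not pass (7 up and 0 down adjusted over the list alone; median 1.00, or 0.24 with signals under 16 set to 16; adjusted p = 0.000654; adjusted p = 0.0173 with an estimated correlation). Fibronectin, FN1, rose 5.87-fold to 2530 ± 220.8, CDH11 2.75-fold, COL5A1 2.50-fold and COL3A1 5.27-fold (0.0522 with the spread taken from all 24 arrays).

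Of 23 estrogen response genes, 9 fell, 2 rose and 12 did not pass in Numb6 cells (4 up and 10 down adjusted over the list alone; median −0.33, adjusted p = 0.000175; adjusted p = 0.0141 with an estimated correlation). GREB1 fell from 2072 ± 170.8 to 801.0 ± 12.5 (2.58-fold, adjusted p = 4.96e-05; 0.0551 with the spread taken from all 24 arrays), EGR3 fell 3.37-fold, the receptor tyrosine kinase gene RET 2.31-fold and OLFM1 2.14-fold (0.331 with the spread taken from all 24 arrays). Of 17 TGF-β targets, 6 rose, 1 fell and 10 did not pass (8 up and 1 down adjusted over the list alone; median 0.50, adjusted p = 0.000819; adjusted p = 0.0472 with an estimated correlation). PMEPA1 rose 2.37-fold, ID1 2.05-fold and TGFB2 3.13-fold. Of 27 Notch receptors, ligands and processing genes, 5 rose and 22 did not pass (6 up and 0 down adjusted over the list alone; adjusted p = 0.000447; adjusted p = 0.0247 with an estimated correlation). DTX4 rose 2.73-fold, ADAM17 1.51-fold, ADAM10 1.42-fold and NOTCH2 1.47-fold. Of 18 epithelial markers, 3 rose and 15 did not pass (5 up and 0 down adjusted over the list alone; adjusted p = 0.00630; adjusted p = 0.0405 with an estimated correlation): KRT7 rose 12.4-fold, ST14 2.16-fold (0.223 with the spread taken from all 24 arrays) and CLDN4 1.71-fold. Of 9 replication-dependent histone genes, 6 fell and 3 did not pass (0 up and 7 down adjusted over the list alone; median −1.003, adjusted p = 5.25e-08; adjusted p = 0.00784 with an estimated correlation). H2AC6 fell 3.88-fold, H2BC12 2.52-fold, H2BC21 2.09-fold and H2BC5 1.86-fold. Of 25 S phase genes, 2 fell and 23 did not pass (0 up and 9 down adjusted over the list alone; median −0.31, adjusted p = 4.12e-06; adjusted p = 0.0481 with an estimated correlation). CCNE2 fell 1.74-fold and MCM6 1.28-fold (adjusted p = 0.101 after quantile normalization).

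The remaining 3 lists were not called with an estimated correlation. Of 21 integrin and focal adhesion genes, 5 rose and 16 did not pass (9 up and 0 down adjusted over the list alone; adjusted p = 7.72e-06, and adjusted p = 0.0505 with an estimated correlation). LAMB3 rose 5.24-fold, ITGA2 1.75-fold, ITGAV 1.62-fold and ZYX 1.59-fold. Of 27 mitosis genes, 3 fell, 1 rose and 23 did not pass (1 up and 11 down adjusted over the list alone; adjusted p = 7.86e-05, and adjusted p = 0.0656 with an estimated correlation): HMMR fell 2.04-fold, NDC80 1.48-fold and TTK 1.42-fold, and MKI67 rose 1.49-fold. Of 20 respiratory chain genes, ATP5F1B fell 1.41-fold and 19 did not pass (0 up and 1 down adjusted over the list alone; adjusted p = 0.0100, 0.224 after quantile normalization, and adjusted p = 0.129 with an estimated correlation). The share of called genes that rose in Numb6 depended on the processing. It was 61.1% in the main fit, 51.9% with a variance trend and 75.7% without the arrays of high beta-actin ratio. In all, 1319 genes changed, 806 up and 513 down, 518 by at least 2-fold, and the groups did not overlap for 26.2% of genes, where chance gives 10%. The count was 792, 812 and 858 without GFP array 1, 2 and 3, 711 and 801 without Numb6 array 2 and 3, and 376 from the 6 arrays alone. From these, GJA1, CFB, DTX4, ADAM17, ZYX, LAMB3, ID1, ATP5F1B and HEY1 were not called (adjusted p 0.0561 to 0.110). Nor were DIRC1, CXCL14, TRIM63, GNB4, RPH3AL-AS1, ADAM10, NOTCH2, ST14, CLDN4, MCM6, HMMR, NDC80, TTK, MKI67, ITGAV, ITGA2 and TGFB2 (0.0800 to 0.211). Without the arrays of high beta-actin ratio these genes but for GJA1 and CFB were not called, nor were TCIM, LINC00504, BPESC1, SPINK6, CDH11, COL5A1, COL3A1, CCNE2 and H2BC5 (0.0528 to 0.310). Of the 66 genes called and named in this comparison, 23 lost their call without at least 1 array. BPESC1, COL3A1, MCM6 and MKI67 did so without each of the 6 arrays in turn, with highest adjusted p of 0.118, 0.131, 0.130 and 0.128. INHBA, DIRC1, CXCL14, GNB4, RPH3AL-AS1, SPINK6, ADAM10, NOTCH2, ST14, CLDN4, NDC80, TTK and ITGA2 did so without 5 of the 6 arrays (highest adjusted p 0.0725, 0.0982, 0.0790, 0.103, 0.131, 0.0720, 0.0813, 0.0911, 0.0979, 0.130, 0.0905, 0.0938 and 0.117). TRIM63, HMMR and TGFB2 did so without 3 arrays (0.0675, 0.0640 and 0.0524), COL5A1 without GFP array 1 or Numb6 array 2 (0.0561) and ITGAV without Numb6 array 2 (0.0516).

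**Figure D2:**
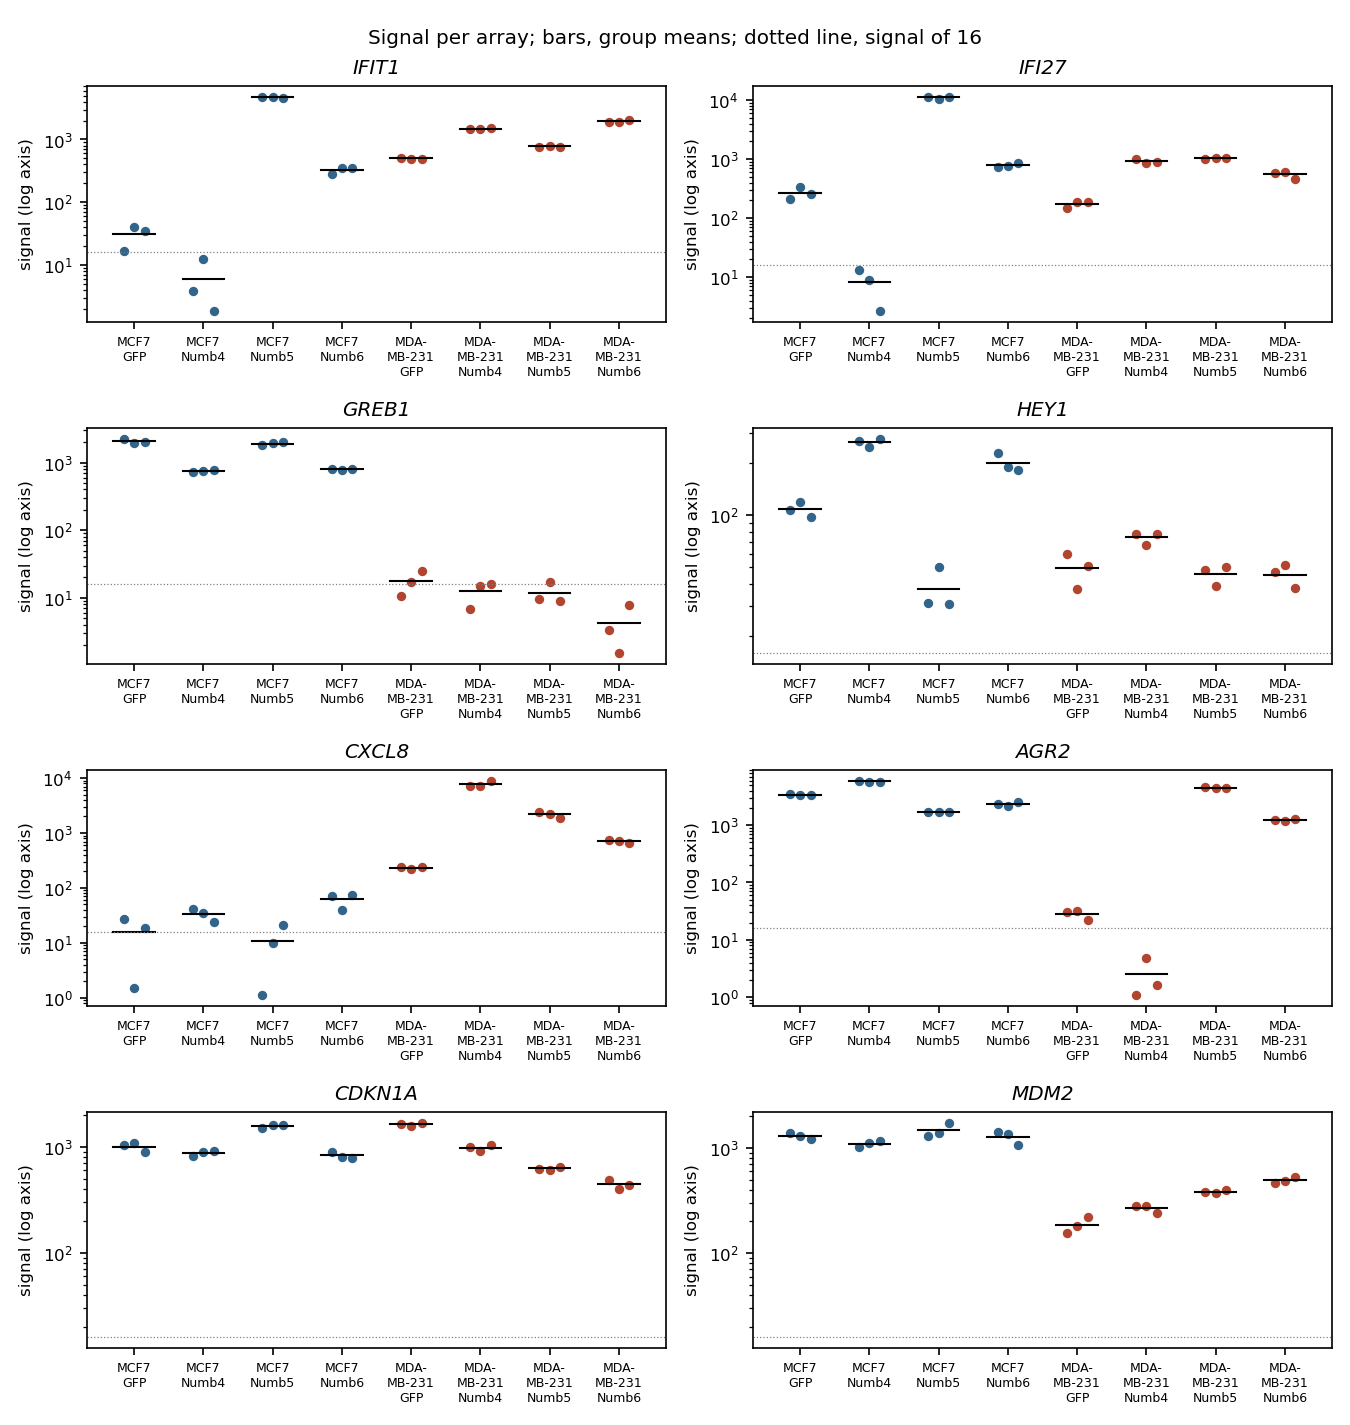
Signal per array (log axis, arbitrary units) of 8 genes in the 8 groups, with a bar at the mean of 3 arrays and a dotted line at a signal of 16. IFIT1 averages 4704 in MCF7 Numb5 against 31.0 in MCF7 GFP, and AGR2 averages 4476 in MDA-MB-231 Numb5 against 28.4 in MDA-MB-231 GFP.

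The 3 forms were then compared with each other in MCF7, since the series asks which changes belong to 1 form. Interferon-stimulated genes set Numb5 apart. IFI27 read 11170 ± 506.4 in Numb5 cells and 8.30 ± 5.35 in Numb4 cells (at least 697-fold). IFIT1, PCDH10, XAF1 and IFI44L were at least 294-, 157-, 47.5- and 20.9-fold higher in Numb5. Of 29 interferon-stimulated genes, 28 were higher in Numb5 than in Numb4 and 1 did not pass (28 up and 1 down adjusted over the list alone; median 3.62, or 3.49 with signals under 16 set to 16; adjusted p = 2.25e-38; adjusted p = 1.67e-05 with an estimated correlation). MARCKS and GJA1 were 53.9- and 51.3-fold lower in Numb5 than in Numb4 (GJA1 with adjusted p = 0.0533 without the arrays of high beta-actin ratio), and UPK3A, ADGRG2 and KRT4 at least 16.4-, 8.25- and 7.71-fold lower. Numb6 also lay above Numb4 for PCDH10, IFI27, IFIT1, PCDH7 and CDKN2B (at least 56.2-, 49.2-, 20.3-, 17.1- and 11.4-fold). From the 6 arrays alone PCDH10, PCDH7 and CDKN2B were not called (adjusted p = 0.0591, 0.0542 and 0.0606). Among the 29 interferon-stimulated genes, 16 were higher in Numb6 than in Numb4 and 13 did not pass (22 up and 1 down adjusted over the list alone; median 1.45, or 0.93 with signals under 16 set to 16; adjusted p = 5.82e-19; adjusted p = 0.000251 with an estimated correlation). The 5 largest falls from Numb4 to Numb6 were in dim genes, EMP1, RIPPLY1, SPMAP1 and C1orf105 (at least 2.70-, 1.69-, 1.33- and 1.08-fold) and TENM1, under 16 in both groups. With signals under 16 set to 16, RIPPLY1, SPMAP1 and C1orf105 were not called (adjusted p = 0.101, 0.142 and 0.791). C1orf105 was not called either with the spread taken from all 24 arrays (0.121). RIPPLY1 lost its call without each of the 6 arrays (highest adjusted p 0.110), TENM1 and EMP1 without 5 (0.126 and 0.122) and C1orf105 without 4 (0.0648). TENM1, EMP1 and RIPPLY1 were also not called from the 6 arrays alone (0.170, 0.177 and 0.0712), nor these and C1orf105 without the arrays of high beta-actin ratio (0.0660 to 0.213).

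Against Numb5, Numb6 cells had DIO2 at least 67.7-fold, UPK3A 7.25-fold and STEAP4 15.7-fold higher, and LCN2 87.0-fold and the collagen gene COL12A1 41.03-fold higher. XAF1, OAS2, IFI44L, ZNF415 and TENM1 were at least 32.6-, 20.6-, 20.9-, 3.49- and 2.74-fold lower, ZNF415 without a call when any of 5 of the 6 arrays was left out (highest adjusted p 0.141) or from the 6 arrays alone (0.131). Without the arrays of high beta-actin ratio ZNF415 and TENM1 were not called (0.243 and 0.0573). Of 29 interferon-stimulated genes, 25 were lower in Numb6 and 4 did not pass (0 up and 26 down adjusted over the list alone; median −2.32, adjusted p = 2.43e-29; adjusted p = 4.73e-05 with an estimated correlation). Of 23 estrogen response genes, 9 were lower and 3 higher (3 up and 12 down adjusted over the list alone; median −0.46, adjusted p = 7.36e-05; adjusted p = 0.0135 with an estimated correlation), of 17 basal and mesenchymal markers 8 were higher and 2 lower (9 up and 3 down adjusted over the list alone; median 1.02, adjusted p = 2.17e-05; adjusted p = 0.0135 with an estimated correlation), and of 19 NF-κB targets 7 were higher (7 up and 0 down adjusted over the list alone; median 0.63, or 0.36 with signals under 16 set to 16; adjusted p = 2.49e-05; adjusted p = 0.0257 with an estimated correlation). Of the 27 lists, 8 passed for Numb5 against Numb4, 10 for Numb6 against Numb4 and 12 for Numb6 against Numb5, and with an estimated correlation 1, 1 and 4 did. The counts of genes were 2492 (1245 up, 1247 down) for Numb5 against Numb4, 797 (530 up, 267 down) for Numb6 against Numb4 and 2403 (1355 up, 1048 down) for Numb6 against Numb5. The second count was 393, 481 and 418 without Numb4 array 1, 2 and 3 and 463, 385 and 411 without Numb6 array 1, 2 and 3, and the last was 1591 without Numb5 array 1 and 1565 without Numb6 array 2. From the 6 arrays alone the counts were 1379, 164 and 889. Among the genes called for Numb6 against Numb4, 66.5% were higher in Numb6. This share was 55.9% with a variance trend and 74.9% without the arrays of high beta-actin ratio.

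**Figure D3:**
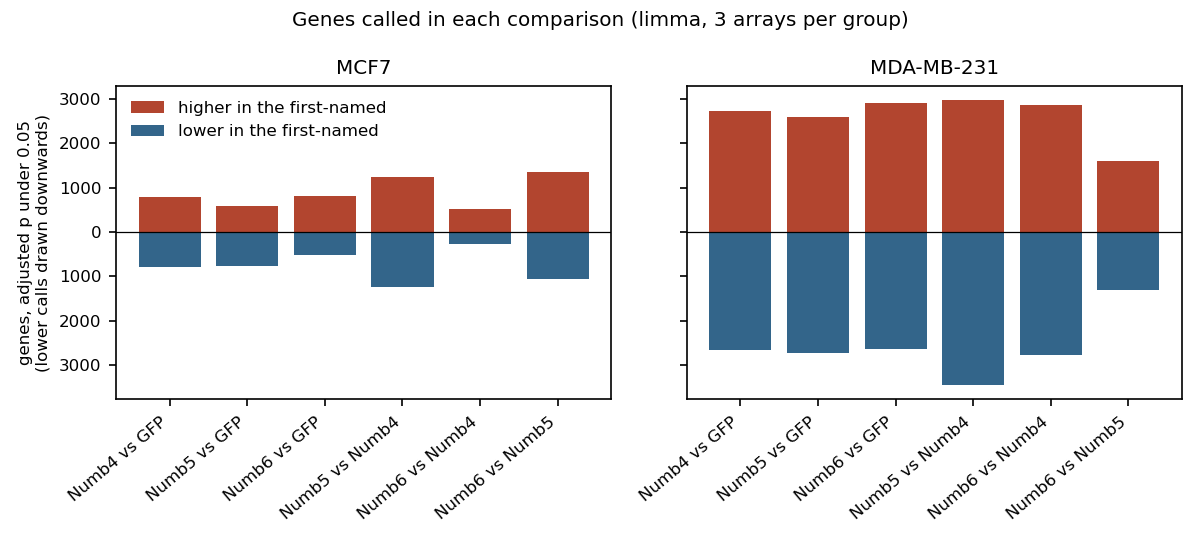
Number of genes up and down at an adjusted p under 0.05 in each comparison of each line, as bars from 0. The comparisons with GFP hold 1319 to 1583 genes in MCF7 and 5320 to 5567 in MDA-MB-231.

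In MDA-MB-231 cells, genes that rose in Numb4 against GFP included the chemokine genes CXCL1, CXCL8, CXCL2 and CXCL3. CXCL1 rose 94.4-fold to 3753 ± 289 (adjusted p = 2.59e-08), CXCL8 33.0-fold to 7795 ± 1014 (adjusted p = 5.09e-08), CXCL2 24.8-fold to 1629 ± 156.6 (adjusted p = 2.04e-08) and CXCL3 at least 17.6-fold. THBS2, a matrix glycoprotein, rose at least 27.0-fold, LINC00960, PLCB4, CYP24A1 and CTSW at least 14.1-, 12.8-, 12.4- and 9.88-fold, and the complement inhibitor gene SERPING1 at least 1.81-fold (adjusted p = 0.0687 with signals under 16 set to 16). NR4A3, an orphan nuclear receptor, fell from 621.3 ± 29.5 to 7.56 ± 3.44 (at least 38.8-fold), GPR183 from 470.8 ± 18.6 to 7.92 ± 3.40 (at least 29.4-fold) and the chemokine receptor gene ACKR3 at least 9.13-fold. TENM3, RADX, SERPINA3, C1QTNF2, SELENOP, CACHD1 and RNF144A fell at least 7.97-, 5.91-, 4.96-, 4.81-, 4.43-, 3.5- and 3.17-fold.

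Of the 27 lists, 6 passed in this comparison and 4 of them with an estimated correlation. Of 19 NF-κB targets, 13 rose and 6 did not pass (13 up and 1 down adjusted over the list alone; median 1.77, or 1.53 with signals under 16 set to 16; adjusted p = 5.00e-10; adjusted p = 0.00571 with an estimated correlation). NFKBIA rose 4.72-fold and the cytokine gene LIF 3.62-fold beside CXCL1 and CXCL2. Of 25 S phase genes, 20 fell, 1 rose and 4 did not pass (1 up and 21 down adjusted over the list alone; median −0.57, adjusted p = 5.00e-10; adjusted p = 0.00571 with an estimated correlation). TYMS, thymidylate synthase, fell from 10114 ± 549.3 to 4242 ± 211.5 (2.38-fold), the helicase cofactor gene CDC45 2.50-fold, the DNA polymerase gene POLA1 2.27-fold and GINS2 2.16-fold. Of 24 genes of the unfolded protein response and ATF4 targets, 13 rose, 1 fell and 10 did not pass (15 up and 2 down adjusted over the list alone; median 0.36, adjusted p = 0.000461; adjusted p = 0.0201 with an estimated correlation). ASNS rose 2.28-fold, TRIB3 2.10-fold, HERPUD1 2.01-fold and MANF 1.75-fold. Of 17 TGF-β targets, 9 fell, 1 rose and 7 did not pass (1 up and 10 down adjusted over the list alone; median −0.50, adjusted p = 0.000461; adjusted p = 0.0436 with an estimated correlation): PMEPA1 fell 3.29-fold to 420.9 ± 43.2, ID3 2.73-fold and BAMBI 1.81-fold, and JUNB rose 3.03-fold. Of 29 interferon-stimulated genes, 14 rose, 4 fell and 11 did not pass (14 up and 6 down adjusted over the list alone; median 0.53, or 0.39 with signals under 16 set to 16; adjusted p = 0.00429, and adjusted p = 0.101 with an estimated correlation). IFI27 rose 5.34-fold, RIGI 4.41-fold, IFI44 3.96-fold and IFIT1 2.97-fold. Of 9 replication-dependent histone genes, 6 rose and 3 did not pass (6 up and 0 down adjusted over the list alone; median 0.70, adjusted p = 0.00420, and adjusted p = 0.0730 with an estimated correlation). H2BC5 rose 3.12-fold, H2BC21 2.64-fold, H2AC6 2.39-fold and H2BC12 1.51-fold. In all, 5388 genes changed, 2728 up and 2660 down, 1558 by at least 2-fold, and the groups did not overlap for 41.8% of genes, where chance gives 10%.

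Numb5 against GFP in MDA-MB-231 showed a rise of AGR2, a protein disulfide isomerase of the endoplasmic reticulum that is usual in luminal cells, from 28.4 ± 5.33 to 4476 ± 128.8 (160-fold, adjusted p = 3.73e-06). The cancer-testis genes MAGEA6 and SPANXB1 rose 122-fold to 3443 ± 63.1 and 71.2-fold to 6440 ± 171 (adjusted p = 3.69e-06 and 1.17e-07). PTGS2, cyclooxygenase 2, rose at least 55.06-fold to 992.8 ± 100.2, and FGF13, SLAMF7, SEL1L3, LINC00960, SFTA3 and PLCB4 rose at least 22.6-, 21.9-, 18.2-, 15.1-, 14.0- and 2.62-fold. The transcription factor gene WT1 fell from 479.2 ± 17.1 to 9.98 ± 1.27 (at least 29.9-fold), the tight junction gene TJP3 from 338.5 ± 31.5 to 3.43 ± 2.22 (at least 21.1-fold), and GPR183, SNHG18, SORCS2 and HCP5 at least 29.4-, 21.9-, 13.4- and 8.85-fold. SERPINA3, MYL1, RNF144A and SEMA5A fell at least 4.96-, 3.18-, 3.17- and 2.98-fold.

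Of the 27 lists, 6 passed in Numb5 cells, and 1 with an estimated correlation. Of 24 genes of the unfolded protein response and ATF4 targets, 14 rose, 2 fell and 8 did not pass (15 up and 2 down adjusted over the list alone; median 0.52, adjusted p = 1.59e-05; adjusted p = 0.0148 with an estimated correlation). The chaperone gene DNAJB9 rose 3.54-fold, ASNS 3.14-fold, TRIB3 2.87-fold and MANF 1.99-fold. Of 19 NF-κB targets, 11 rose, 3 fell and 5 did not pass (12 up and 3 down adjusted over the list alone; adjusted p = 0.00115, and adjusted p = 0.0604 with an estimated correlation). CXCL2 rose 3.99-fold, LIF 3.21-fold, CXCL1 3.06-fold and CCL20 at least 2.65-fold. Of 25 S phase genes, 12 fell, 1 rose and 12 did not pass (1 up and 12 down adjusted over the list alone; adjusted p = 0.00242, and adjusted p = 0.0604 with an estimated correlation). TYMS fell 2.10-fold, GINS2 1.83-fold, MCM4 1.80-fold and POLA1 1.59-fold. Of 23 estrogen response genes, 8 rose, 1 fell and 14 did not pass (8 up and 1 down adjusted over the list alone; median 0.24, or 0.12 with signals under 16 set to 16; adjusted p = 0.0213, and adjusted p = 0.0779 with an estimated correlation). SLC7A2 rose 7.64-fold, TFF1 6.14-fold, NRIP1 2.54-fold and CTSD 2.43-fold. Of 9 replication-dependent histone genes, 6 fell and 3 did not pass (0 up and 6 down adjusted over the list alone; median −1.11, adjusted p = 0.000281, and adjusted p = 0.0521 with an estimated correlation). H1-2 fell 3.59-fold, H2BC12 2.50-fold, H2BC5 2.24-fold and H2AC6 2.16-fold. Of 11 fibroblast markers, fixed as a sign of another cell type, 5 fell and 6 did not pass (0 up and 5 down adjusted over the list alone; median −0.58, or −0.31 with signals under 16 set to 16; adjusted p = 0.00242, and adjusted p = 0.0521 with an estimated correlation). TAGLN and COL6A3 fell 22.0- and 17.1-fold to 36.0 ± 8.32 and 43.2 ± 3.78, MYL9 fell 2.55-fold and FBLN1 at least 1.90-fold (adjusted p = 0.0831 with signals under 16 set to 16). In all, 5320 genes changed, 2601 up and 2719 down, 1555 by at least 2-fold, and the groups did not overlap for 41.9% of genes, where chance gives 10%.

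Numb6 against GFP in MDA-MB-231 raised many of the genes raised in Numb5 cells. SPANXB1 rose 99.3-fold to 8983 ± 333.7 (adjusted p = 7.72e-08) and AGR2 43.5-fold to 1219 ± 61.8 (adjusted p = 2.09e-05). GKN2, SLAMF7, LINC00261, LINC00960, SFTA3, SEL1L3, the inflammasome gene NLRP2 and EPB41L3 rose at least 31.8-, 27.0-, 19.6-, 14.1-, 12.4-, 11.5-, 8.91- and 1.54-fold. NR4A3, WT1, GPR183, SNHG18 and APCDD1L fell at least 38.8-, 29.9-, 29.4-, 21.9- and 20.2-fold, and ACKR3, HCP5, SERPINA3, RNF144A and MAGEA11 at least 9.13-, 8.85-, 4.96-, 3.17- and 2.24-fold.

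Of the 27 lists, 7 passed in Numb6 cells and 2 of them with an estimated correlation. Of 29 interferon-stimulated genes, 19 rose, 4 fell and 6 did not pass (19 up and 5 down adjusted over the list alone; median 0.82, adjusted p = 1.21e-05; adjusted p = 0.0408 with an estimated correlation). IFIT1 rose 3.91-fold to 1948 ± 101.1, IFIT2 3.81-fold (adjusted p = 0.0691 with the spread taken from all 24 arrays), OASL 3.24-fold and IFI44 2.82-fold. Of 25 S phase genes, 16 fell, 2 rose and 7 did not pass (2 up and 17 down adjusted over the list alone; median −0.43, adjusted p = 7.34e-07; adjusted p = 0.0223 with an estimated correlation). TYMS fell 1.93-fold, POLA1 1.88-fold, MCM6 1.80-fold and RRM2, a subunit of ribonucleotide reductase, 1.77-fold. Of 16 cholesterol synthesis genes, 7 fell, 2 rose and 7 did not pass (2 up and 7 down adjusted over the list alone; adjusted p = 0.0134, and adjusted p = 0.0773 with an estimated correlation). INSIG1 fell 2.73-fold, IDI1 2.39-fold and SC5D 1.87-fold, and NSDHL rose 2.204-fold. Of 19 NF-κB targets, 9 rose, 2 fell and 8 did not pass (10 up and 2 down adjusted over the list alone; adjusted p = 0.0275, 0.0638 with signals under 16 set to 16, and adjusted p = 0.182 with an estimated correlation). LIF rose 3.47-fold, TNFAIP3 3.43-fold and NFKBIA 1.74-fold, and CD83 fell 2.41-fold. Of 9 replication-dependent histone genes, 6 fell, 1 rose and 2 did not pass (1 up and 6 down adjusted over the list alone; median −1.16, adjusted p = 0.00385, and adjusted p = 0.0773 with an estimated correlation). H1-2 fell 2.66-fold, H2AC6 2.33-fold, H2BC12 2.32-fold and H2BC5 2.24-fold. Of 11 fibroblast markers, 3 fell and 8 did not pass (0 up and 3 down adjusted over the list alone; adjusted p = 0.0266, 0.0947 with signals under 16 set to 16, and adjusted p = 0.110 with an estimated correlation): COL6A3 fell 34.9-fold, TAGLN 12.4-fold and MYL9 2.63-fold.

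Of 20 ribosomal protein genes, RPL14, RPL32 and RPS9 rose 1.27-, 1.27- and 1.18-fold and 17 did not pass (0 up and 0 down adjusted over the list alone). The list passed at an adjusted p of 0.0134, with 0.520 after quantile normalization, 0.0872 without GFP array 2 and adjusted p = 0.728 with an estimated correlation. Without 1 array at a time, RPL14, RPL32 and RPS9 reached adjusted p of 0.0737, 0.127 and 0.124 and lost their calls without 4, 5 and 5 of the 6 arrays. RPS9 was not called with the spread taken from all 24 arrays (0.0502), and none of these 3 from the 6 arrays alone (0.0750, 0.0831 and 0.125). In all, 5567 genes changed in Numb6 cells, 2920 up and 2647 down, 1786 by at least 2-fold, and the groups did not overlap for 41.9% of genes, where chance gives 10%.

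Between the forms in MDA-MB-231, AGR2, CDH11, PTGS2, ADAMTS1 and SLAMF7 set Numb5 above Numb4. CDH11, a cadherin of mesenchymal cells, read 3545 ± 41.8 in Numb5 cells and 9.29 ± 4.04 in Numb4 cells (at least 222-fold), AGR2 was at least 280-fold, PTGS2 61.8-fold, ADAMTS1 45.6-fold and SLAMF7 21.9-fold higher. FAT3, PAK6, TJP3, CTSW and HCP5 were at least 59.6-, 20.02-, 18.2-, 9.88- and 5.03-fold lower. Numb6 lay above Numb4 for SPANXB1 (228-fold), CDH11 (at least 151-fold), AGR2 (at least 76.1-fold), ADAMTS1 (at least 54.4-fold) and SLAMF7 (at least 27.0-fold), and below it for APCDD1L, the complement gene C3, THBS2, WT1 and HCP5 (at least 48.9-, 40.1-, 27.0-, 11.1- and 5.03-fold). Numb6 and Numb5 differed in NAP1L3 and GSPT2 (at least 13.7- and 9.19-fold higher in Numb6), PAGE5 and ALPP (at least 2.17- and 2.00-fold), and NTM, NR4A3, PLCB1, C3 and LRCH2 (at least 25.7-, 13.4-, 12.02-, 11.7- and 2.53-fold lower). PABPC5, under 16 in both groups, lost its call with the spread taken from all 24 arrays (adjusted p = 0.0688) and without 4 of the 6 arrays and LRCH2 without 5 (highest adjusted p 0.0866 and 0.0746). From the 6 arrays alone they were not called (0.0791 and 0.0571). NF-κB targets were lower in both Numb5 (10 lower, 2 higher of 19; 2 up and 11 down adjusted over the list alone; adjusted p = 0.00126, and adjusted p = 0.0839 with an estimated correlation) and Numb6 (10 lower of 19; 10 lower and 1 higher adjusted over the list alone; adjusted p = 4.77e-06, and adjusted p = 0.0508 with an estimated correlation) than in Numb4. In Numb6 against Numb5, 13 of 29 interferon-stimulated genes were higher and 2 lower (14 up and 2 down adjusted over the list alone; adjusted p = 1.01e-05, and adjusted p = 0.0538 with an estimated correlation). Of the 27 lists, 5, 3 and 8 passed in the 3 comparisons between forms, and 0 with an estimated correlation. The counts were 6426 genes (2974 up, 3452 down) for Numb5 against Numb4, 5638 (2870 up, 2768 down) for Numb6 against Numb4 and 2906 (1597 up, 1309 down) for Numb6 against Numb5. In the first of these the median log2 change of all genes was −0.12, and −0.06 after quantile normalization. The last count was 1573 from the 6 arrays alone.

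**Figure D4:**
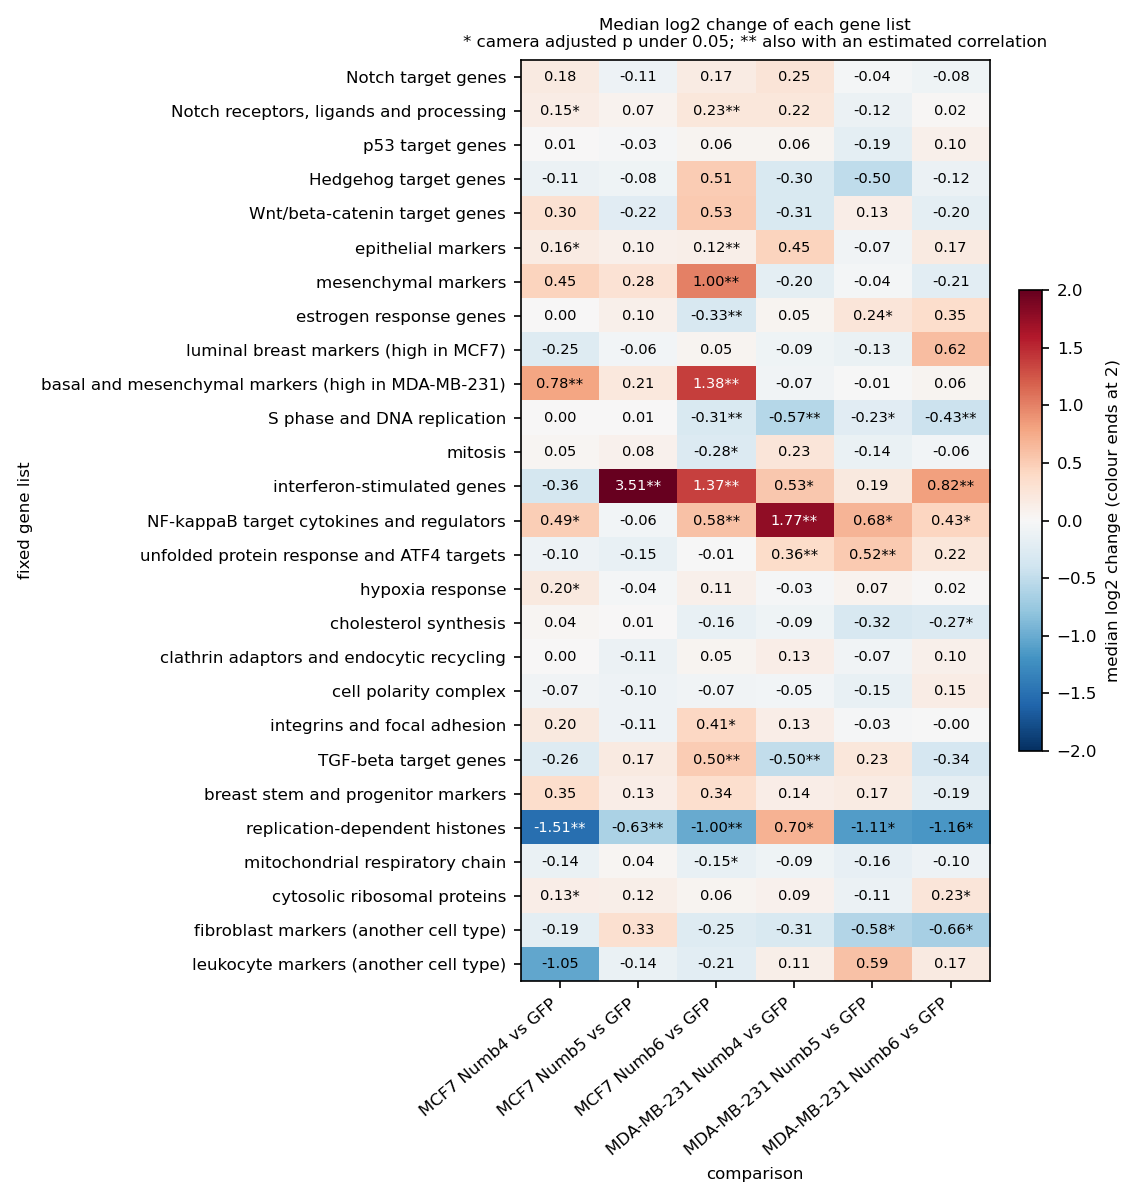
Median log2 change against GFP of each of the 27 gene lists in the 6 comparisons of a form with GFP, as a colour scale, with 1 star where the list passed at an adjusted p under 0.05 and 2 stars where it also passed with an estimated correlation. Interferon-stimulated genes in MCF7 Numb5 hold a median of 3.51.

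Genes of the Notch and p53 pathways were examined by name in every form, since NUMB is known to act on Notch receptors and to bind p53 and its ubiquitin ligase MDM2. The Notch target gene HEY1 changed in each MCF7 form: it rose 2.45-fold in Numb4 cells (264.9 ± 15.8 against 108.4 ± 10.9, adjusted p = 0.00348) and 1.86-fold in Numb6 cells (201.4 ± 24.5, adjusted p = 0.0258), and fell 2.97-fold in Numb5 cells (37.4 ± 10.99, adjusted p = 0.00127, and 0.0535 without the arrays of high beta-actin ratio). The Numb6 call of HEY1 was lost after quantile normalization (adjusted p = 0.0547) and without each of the 6 arrays in turn (0.0521 to 0.0862). HES1, another Notch target, did not pass in MCF7 (log2 changes −0.08, −0.27 and −0.14 for Numb4, Numb5 and Numb6, adjusted p = 0.767, 0.213 and 0.565). In MDA-MB-231, HES1 fell 2.55-fold in Numb6 cells to 81.1 ± 6.91 (adjusted p = 1.66e-05) and 1.43-fold in Numb4 cells (adjusted p = 0.00528), with 0.04 in Numb5 (adjusted p = 0.853). HEY1 rose 1.53-fold in MDA-MB-231 Numb4 cells (adjusted p = 0.0374, lost without any array but GFP array 1, highest 0.112, and from the 6 arrays alone, 0.0951), with −0.09 in Numb5 and −0.11 in Numb6. Of 14 Notch target genes as a list, 2 rose in MCF7 Numb4 and 12 did not pass (3 up and 1 down adjusted over the list alone; adjusted p = 0.0657), and the list did not pass in any comparison of a form with GFP. NOTCH1 did not pass in any form, with log2 changes of −0.44, 0.07 and 0.06 in MCF7 and 0.64, −0.21 and 0.23 in MDA-MB-231 for Numb4, Numb5 and Numb6. In MDA-MB-231 Numb4 it did pass with a variance trend (adjusted p = 0.0298) and with the spread taken from all 24 arrays (0.0312). The related gene NUMBL did not pass either, with −0.40, 0.17 and 0.57 in MCF7 and 0.24, 0.35 and 0.40 in MDA-MB-231.

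CDKN1A, the cell cycle inhibitor p21 and a p53 target, fell in all 3 forms of MDA-MB-231, from 1627 ± 60.8 to 978.5 ± 60.8 in Numb4 (1.66-fold, adjusted p = 0.000358), 623.4 ± 22.8 in Numb5 (2.61-fold, adjusted p = 8.06e-06) and 441.1 ± 47.7 in Numb6 (3.70-fold, adjusted p = 1.25e-06). MDM2 rose in the same cells, from 184.8 ± 32.0 to 266.9 ± 23.1 (1.46-fold, adjusted p = 0.0112, and 0.0762 from the 6 arrays alone), 382.5 ± 12.6 (2.09-fold, adjusted p = 0.000260) and 492.3 ± 33.2 (2.69-fold, adjusted p = 3.87e-05). In MCF7, CDKN1A rose 1.57-fold in Numb5 cells to 1573 ± 61.0 (adjusted p = 0.00689) and did not pass in Numb4 (−0.20, adjusted p = 0.348) or Numb6 (−0.27, adjusted p = 0.192), and MDM2 did not pass in any form (−0.25, 0.17 and −0.04, adjusted p = 0.386, 0.589 and 0.912). Of 23 p53 targets in MDA-MB-231, 6 rose and 4 fell in Numb4, 7 rose and 6 fell in Numb5 and 6 rose and 5 fell in Numb6, and the list did not pass in any comparison of a form with GFP. Whether p53 takes part in the changes of CDKN1A and MDM2 was not tested. TP53, which the rule named, has no probe set with that symbol in the annotation used and was not analysed here.

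Across the 4 transfections of a line, the moderated F-test called 3468 genes in MCF7 (17.5%) and 8721 in MDA-MB-231 (44.1%). Genes changed against GFP in the same direction in all 3 forms numbered 230 in MCF7 (118 up, 112 down) and 1688 in MDA-MB-231 (870 up, 818 down), where independent draws of the same counts would give 1.76 and 102. Simulated groups without any change gave 0, but at most 1 and 2 calls in a comparison, too few to share. Part of the excess may come from the shared GFP arrays. Numb4 and Numb6 shared 688 changed genes in MCF7 in the same direction (expected 52.7) with 23 in opposite directions, Numb4 and Numb5 shared 357 (expected 54.4) with 94 opposite, and Numb5 and Numb6 shared 367 (expected 43.9) with 63 opposite. In MDA-MB-231, Numb5 and Numb6 shared 3539 (expected 748) with 96 opposite, Numb4 and Numb6 2474 (expected 759) with 615 opposite, and Numb4 and Numb5 2079 (expected 725) with 781 opposite. Across genes with bright signals, which are not independent replicates, the log2 changes of Numb4 and Numb6 in MCF7 correlated at r = 0.669 and those of Numb5 and Numb6 in MDA-MB-231 at r = 0.802, where simulated unchanged groups with shared controls gave about 0.50. The covariance for those pairs was 0.156 and 0.338, against 0.0128 and 0.00762 simulated. For the other pairs r was 0.253 (Numb4 and Numb5) and 0.349 (Numb5 and Numb6) in MCF7, with covariances of 0.0618 and 0.0749 against 0.0128 and 0.0129 simulated, and 0.285 (Numb4 and Numb5) and 0.423 (Numb4 and Numb6) in MDA-MB-231, with 0.114 and 0.170 against 0.00764 and 0.00760. Genes called in 1 form only numbered 1926 in MCF7 and 3686 in MDA-MB-231, which does not show that the other forms differ. The count for all 3 forms in MCF7 was 147 and 132 without GFP array 1 and 2, 142 and 147 without Numb5 array 1 and 3, and 144 without Numb6 array 2.

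Effects of a form were compared between the lines through the difference of the 2 log2 changes. IFI27 fell in MCF7 Numb4 cells by 5.28 on the log2 scale and rose in MDA-MB-231 Numb4 cells by 2.42, AGR2 fell in MCF7 Numb5 cells by 0.99 (from 3377 to 1698) and rose in MDA-MB-231 by 7.32, and PSMB8 rose in MCF7 Numb5 cells by 6.75 and fell in MDA-MB-231 by 1.25. The effect differed between the lines for 3985 genes with Numb4, 4293 with Numb5 and 3835 with Numb6. Genes called in the same direction in both lines numbered 382 for Numb4 (expected 216), 254 for Numb5 (expected 183) and 385 for Numb6 (expected 188), and genes called in opposite directions 317, 381 and 299 (expected 216, 182 and 184). Across 8181 genes with bright signals, the log2 changes of the 2 lines correlated at r = 0.00452, −0.0735 and 0.0794. The same-direction count was 251 for Numb4 without MCF7 Numb4 array 1, 169 and 166 for Numb5 without MCF7 GFP array 2 and MCF7 Numb5 array 1, and for Numb6 221, 233 and 256 without MCF7 GFP array 1, 2 and 3 and 202 and 240 without MCF7 Numb6 array 2 and 3.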

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

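The results below were marked because the effect of a Numb form differed between the 2 cell lines, tested as the difference of the 2 log2 changes (MDA-MB-231 minus MCF7), and the tests for MDA-MB-231 cells in the MCF7 Numb5 culture, for an effect of Numb5 of like size in both lines, for MCF7 cells in the MDA-MB-231 cultures, for the noise of shared GFP arrays and for arrays exchanged between the lines were chosen after the result was seen. The effect differed for 3985 genes with Numb4, 4293 with Numb5 and 3835 with Numb6. Of 100 exchanges of arrays between the lines within a transfection, each line centred, 1 gave as many genes for each form, the real one, and the highest other gave 2. Spread between arrays alone can therefore be excluded for all 3 differences. Exchanged arrays cannot exclude a chance difference between transfected lines, since the replicates may not be independent transfections. Other splits mixed form and GFP arrays within each line, which tests for an effect in either line and not for a difference between them. There 2 of 100 gave as many genes as the real one for Numb4 and 1 each, the real one, for Numb5 and Numb6. Spread between arrays alone can therefore be excluded for a difference from GFP in either line, with the same limit. The highest other gave 4152, 2643 and 2691. The 4152 came from the split that swaps the Numb4 and GFP labels in 1 line and keeps both effects, and the next highest gave 2427. That swap was not among the splits drawn for Numb5 and Numb6, where it gave 3647 and 4184, the latter above the real count.

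For Numb4, the difference was 9.10 for PLCB4, 7.69 for IFI27, 6.49 for ADAMTS9, 6.42 for LINC00960 and 6.41 for PLCXD3, and −11.51 for RNF128, −9.60 for GJA1, −8.61 for ALOX5, −8.22 for RADX and −7.41 for CEACAM5. RNF128 rose to 122.1 in MCF7 from a signal under 16 and fell in MDA-MB-231 from 38.2 to under 16, and ALOX5, which makes leukotrienes, changed by 4.67 on the log2 scale in MCF7 and by −3.94 in MDA-MB-231. GJA1 changed by 8.77 in MCF7 and −0.83 in MDA-MB-231. Each of the 30 differences given for genes here and below passed, with adjusted p up to 0.0431. Most involve a group mean under 16, so their size is uncertain. Among the lists, the median difference was 2.22 for replication-dependent histones, 1.31 for NF-κB targets, 0.64 for interferon-stimulated genes and 0.35 for the unfolded protein response, and −1.09 for mesenchymal markers, −0.62 for basal and mesenchymal markers and −0.56 for S phase genes. With signals under 16 set to 16, the NF-κB and mesenchymal medians were 0.72 and −0.49.

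For Numb5, the difference was 8.93 for FGF13, 8.31 for AGR2, 8.05 for MAGEA6, 7.63 for STEAP4 and 7.16 for SFTA3, and −10.36 for HCP5, −8.28 for SNHG18, −8.00 for PSMB8, −7.35 for RNF144A and −7.07 for SORCS2. FGF13 fell from 652.6 to 124.0 in MCF7 and rose from under 16 to 362.0 in MDA-MB-231, and HCP5 changed by 3.499 in MCF7 and −6.86 in MDA-MB-231. The call for SFTA3 was lost without any of 4 of the 12 arrays (highest adjusted p 0.0702) and from the 12 arrays alone (0.0652). The median difference was −3.71 for interferon-stimulated genes, 0.66 for the unfolded protein response and −1.08 for fibroblast markers (−0.56 with signals under 16 set to 16).

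For Numb6, the difference was 7.56 for LINC00261, 7.28 for GKN2, 6.75 for LINC00960, 6.58 for SPANXB1 and 6.49 for SFTA3, and −8.69 for SNHG18, −8.12 for TCIM, −7.71 for WT1, −7.61 for NR4A3 and −7.58 for ALOX5. The call for SFTA3 was lost without any of 8 of the 12 arrays (highest adjusted p 0.124) and from the 12 arrays alone (0.114). The median difference was −1.10 for basal and mesenchymal markers, −0.93 for TGF-β targets, −0.68 for interferon-stimulated genes and for mesenchymal markers, and 0.32 for the unfolded protein response. With signals under 16 set to 16, the interferon and mesenchymal medians were −0.42 and −0.24.

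Interferon-stimulated genes were higher in MCF7 Numb5 cells than in GFP cells, 27 of 29 of them with a median log2 change of 3.51. Array scaling is argued against by a median of 3.48 after quantile normalization. MDA-MB-231 cells in the culture are argued against by the levels, since 70.4% of the risen members (19 of 27) lay above the mean of every MDA-MB-231 group. An effect of Numb5 of like size in both lines is argued against by the median difference of −3.71, although 18 of the 29 genes were already higher in MDA-MB-231 GFP cells than in MCF7 GFP cells. An interferon response set off by Numb5 in MCF7 and a difference of this 1 transfected line both stay open as hypotheses, and no test here separates them.

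Many genes changed the same way against GFP in all 3 forms of a line. Chance from the shared GFP arrays was not decided by simulated groups without any change, whose highest count was 0 because at most 2 genes were called. Noise of these arrays as the whole cause is argued against by comparing each form with a different GFP array: at the lowest of 6 assignments 81.48% in MCF7 and 81.52% in MDA-MB-231 of the genes called in all 3 forms changed in 1 direction, where independent directions give at most 31.6% and 25.4%. A candidate explanation is that each transfected line differs on its own. Of the genes past the F-test with 1 group clearly apart from the other 3, GFP was that group in 17.6% in MCF7 (320 of 1815) and 29.7% in MDA-MB-231 (1338 of 4510). The Numb4, Numb5 and Numb6 groups held 21.8%, 44.4% and 16.2% in MCF7 and 39.5%, 17.1% and 13.7% in MDA-MB-231. GFP thus stood apart less often than the form that did so most, but in MDA-MB-231 more often than Numb5 and Numb6. These shares are not limited to the genes shared by all 3 forms, so they do not decide the question for those genes. An effect common to the forms and a difference of the GFP line from the rest stay open.

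AGR2 and a few other genes of MCF7 cells appeared in MDA-MB-231 Numb5 and Numb6 cells, AGR2 at 132.6% and 36.1% of its MCF7 GFP level. MCF7 cells in these cultures are argued against by 13 other transcripts over 2000 in MCF7 GFP and under 50 in MDA-MB-231 GFP, which reached a median of 0.366% of their MCF7 level in Numb5 and 0.203% in Numb6, or 0.0770% and 0.0459% (AGR2 132.8% and 35.6%) with the MDA-MB-231 GFP level subtracted, among them DSCAM-AS1 (11990 in MCF7 and 8.51 in Numb5) and CDH1 (8007 and 5.73), genes chosen after their values were seen. Array scaling is argued against by the smaller of the 2 log2 changes of AGR2 after quantile normalization, 5.44. Of the 13 transcripts, 3 rose in Numb5 cells (MAL2 to 460.8, LDOC1 to 278.3 and SLC7A2 to 271.2), and in Numb6 cells 4 rose (MAL2 to 496.4, LDOC1 to 354.2, SLC7A2 to 71.5 and CLDN3 to 32.5) and GREB1 fell, also chosen after their values were seen. A change of gene expression with these forms and a difference of the transfected lines stay open.

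For the comparisons of 2 groups of 3 arrays, the 10 splits of the 6 arrays are too few for a share under 0.05, and in each 1 of the 10, the real one, gave as many genes. In MCF7, the real and highest other counts were 1583 and 0 for Numb4 against GFP, 1359 and 1 for Numb5, 1319 and 3 for Numb6, 2492 and 0 for Numb5 against Numb4, 797 and 2 for Numb6 against Numb4, and 2403 and 1 for Numb6 against Numb5. In MDA-MB-231 they were 5388 and 1, 5320 and 1, 5567 and 2, 6426 and 1, 5638 and 4, and 2906 and 3 in the same order, and 9939 and 2 for the GFP cells of the 2 lines. For the 4 transfections of a line, 1 of 100 splits, the real one, gave as many genes. The counts were 3468 in MCF7, with 278 as the highest other, and 8721 in MDA-MB-231, with 2284. Spread between arrays alone can therefore be excluded, but not a chance difference between transfected lines.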

How the results depend on the processing

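Setting signals under 16 to 16 and leaving out the 3 MCF7 arrays of high beta-actin ratio were tests chosen after the data were seen. Each of the 23 counts of genes stayed within 1.5 times under quantile normalization, and no result reversed its direction where it had passed, under any alternative run. The NUMB probe set values kept their side of the threshold under quantile normalization and without 1 array at a time. Signal over background limits the dim genes: where a group mean lies under 16, the size of a fitted change is uncertain. Of 434 values of named genes, quantile normalization left 429 on the same side of the threshold, and 3 were no longer past it and 2 newly past it. Leaving out 1 array at a time left 2576 of 2784 such values on the same side and 208 no longer past it, the replicate block took 23 of 434, the arrays compared alone 62 of 422 and the set without high-actin arrays 57 of 197 below it. The replicate numbers do not pair the samples: residuals of arrays with the same number correlated at −0.194 to 0.129 in MCF7 (median −0.00914) and −0.239 to 0.119 in MDA-MB-231 (median −0.0134), over 18 pairs each. Except for those with fewer arrays, the cause of each change below was not tested.

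Counts in MCF7 are given for Numb4, Numb5 and Numb6 against GFP and for Numb5 against Numb4, Numb6 against Numb4 and Numb6 against Numb5, where they moved by over 1.5 times. With a variance trend the first 3 were 2456, 2272 and 2315 and Numb6 against Numb4 was 1694. With the spread from all 24 arrays they were 2477, 2283, 2368 and 1757, and the F-test count was 5475. From the arrays compared alone, which are fewer, the 6 counts were 705, 507, 376, 1379, 164 and 889, and Numb6 against Numb5 in MDA-MB-231 was 1573. With the replicate block, Numb6 against GFP was 822 and Numb6 against Numb4 was 440. Without the dimmest genes, Numb5 against GFP was 2051 and Numb6 against Numb4 was 1411. With signals under 16 set to 16, Numb5 and Numb6 against GFP were 2142 and 2096 and Numb6 against Numb4 was 1538. Genes shared by all 3 MCF7 forms were then 385 and by both lines 610, 445 and 631 for Numb4, Numb5 and Numb6. Without the high-actin arrays the 6 counts were 726, 421, 313, 1304, 171 and 731, the F-test count 1215, the count for all 3 forms 52 and those for both lines 156, 86 and 96. Leaving out other choices of 3 arrays from the same groups (26 of them) gave 648 to 830, 367 to 490, 271 to 424, 1185 to 1481, 136 to 233 and 574 to 960 for the 6 counts, so the drop goes with fewer arrays.

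With every probe set tested, counts in MDA-MB-231 rose with the number tested to 8659, 8538 and 8994 for Numb4, Numb5 and Numb6 against GFP, 11282 and 9108 for Numb5 and Numb6 against Numb4 and 15629 in the F-test, the GFP cells differed at 20399 probe sets and the effect of Numb5 differed between lines at 6556. With an absolute log2 change of at least 0.58, 844 genes were shared by all 3 forms in MDA-MB-231 and 207, 143 and 225 by both lines. Without 1 array at a time, which leaves a group of 2, the MCF7 counts that moved ran from 816 to 958 for Numb5 and 711 to 951 for Numb6 against GFP, 385 to 481 for Numb6 against Numb4 and 1565 to 1870 for Numb6 against Numb5. Those for all 3 forms ran from 132 to 166 and for both lines from 251 to 352, 166 to 236 and 202 to 348.

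Of 41 list results against GFP, 20 were not past the threshold with an estimated correlation. In MCF7 Numb4 the adjusted p was then 0.147 for Notch receptors, ligands and processing, 0.0720 for epithelial markers, 0.105 for NF-κB targets, 0.322 for hypoxia and 0.533 for ribosomal proteins, and in MCF7 Numb6 0.0656 for mitosis, 0.0505 for integrins and 0.129 for the respiratory chain. In MDA-MB-231 it was 0.101 for interferon-stimulated genes and 0.0730 for histones in Numb4. In Numb5 it was 0.0779 for estrogen response genes, 0.0604 for S phase genes and for NF-κB targets and 0.0521 for histones and for fibroblast markers. In Numb6 it was 0.182 for NF-κB targets, 0.0773 for cholesterol synthesis and for histones, 0.728 for ribosomal proteins and 0.110 for fibroblast markers. Quantile normalization ended the ribosomal calls in MCF7 Numb4 (0.104) and MDA-MB-231 Numb6 (0.520) and the respiratory chain call in MCF7 Numb6 (0.224), and signals under 16 set to 16 ended the NF-κB (0.0638) and fibroblast (0.0947) calls in MDA-MB-231 Numb6. Without 1 array at a time the adjusted p in MCF7 Numb4 ran from 0.0175 to 0.106 for the Notch list, 0.0104 to 0.114 for hypoxia and 0.0110 to 0.104 for ribosomal proteins, and in MDA-MB-231 Numb6 from 0.00658 to 0.0872 for ribosomal proteins.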

Other observations

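No test in this part was chosen to explain the genes below, which were chosen after their values were seen. In all 6 comparisons of a form with GFP, 17 genes were called in the same direction, 8 up and 9 down. The 3 comparisons of a line share GFP arrays, so independent draws give no baseline. GDF15, a stress-induced cytokine of the TGF-β family, changed by 1.524, 1.608 and 1.205 on the log2 scale in MCF7 Numb4, Numb5 and Numb6 cells and by 0.822, 3.494 and 3.09 in the MDA-MB-231 cells. PXDN, a peroxidase of the extracellular matrix, changed by 1.565, 1.381 and 1.624 and by 1.719, 2.421 and 2.507 in the same order, and OASL, an interferon-stimulated gene, by 1.443, 3.511 and 1.815 and by 1.231, 0.96 and 1.696. DMKN, FILIP1L, MAN1A1, SAT1 and TES were the other genes that rose.

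The chemokine gene CXCL14 changed by −5.07, −4.024 and −4.064 in the MCF7 cells and by −3.166, −3.14 and −2.632 in the MDA-MB-231 cells. As given above, its call was lost without each of the 6 arrays in MCF7 Numb5 and 5 of them in MCF7 Numb6. The small GTPase gene RAP1A changed by −3.473, −0.684 and −1.188 and by −3.585, −2.468 and −2.751. KITLG, the ligand of the receptor KIT, changed by −2.21, −0.825 and −0.747 and by −2.063, −0.747 and −2.127, and the chemokine receptor gene ACKR3 by −1.025, −0.981 and −0.748 and by −6.954, −4.726 and −7.427, with ACKR3 at group means under 16 in each MDA-MB-231 form. SLC26A2, a sulfate transporter, NUCB2, C1orf21, ADI1 and FAM217B were the other genes that fell.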
